A study of Homo sapiens with 19 samples.

How the data were processed

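Gene expression was measured on 19 arrays in primary human aortic endothelial cells (EC) and vascular smooth muscle cells (VSMC) that had been cultured for 24 h on flat titanium or on titanium covered with upright titanium dioxide nanotubes. Nanotubes had a pore diameter of 30 nm (NT30) or 100 nm (NT100). Groups and replicate numbers were taken from the labels: 4 arrays each of EC on flat titanium, EC on NT30 and EC on NT100, 4 of VSMC on flat titanium and 3 of VSMC on NT30. The labels' protocols give 400 ng of RNA per sample and labelling with 1 dye, Cy3. The sources used here call the samples biological replicates but do not say that they came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical.

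The deposited scanner tables hold spot intensity on a linear scale, per the file headers. Processed intensity had been made by Agilent Feature Extraction with spatial and multiplicative detrending, with replacement values for spots near background, and had not been scaled between arrays, per the file headers. Version 9.5.1.1 of that software is recorded for the EC arrays and version 10.1.1.1 for the VSMC arrays, per the file headers, while the submitters' processing notes name version 10.1. EC and VSMC samples lay on different array designs, with 45015 and 38283 spots, and were read on different scanner models, so cell type cannot be told apart from array design and scan. A deposited table of the whole series holds values on a log2 scale, as seen from the values themselves. Its EC columns (medians 7.07 to 7.08) correlated with the log2 median signal of their own arrays at r of 0.998 or more across probes, and were quantile normalized. Its VSMC columns (medians 7.4 to 7.415) correlated at about -0.002 when matched by probe name, so they were not used. What scaling preceded that normalization is not given in the sources used here. The values have the orientation of the signal in the EC columns, and that of the VSMC columns stays unknown.

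Probe names came from the arrays' own annotation. Of 41000 probes on the EC design, 23782 were named by matching their accession, without version, to a table of RefSeq genes, 1865 by a current symbol and 960 by an older symbol, and 14289 kept the name in the annotation. In all, 17440 gene symbols were measured, and 12 probes had different names on the 2 designs. All 36866 probes of the VSMC design are also on the EC design. Probe positions are those of the EC design on genome build hg17, while the VSMC design gives hg18. No genome sequence was used, so exons and untranslated regions are not annotated.

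Log2 of the processed intensity minus the array's own 75th percentile was the value tested. That percentile ranged from 412.4 to 1008.8 intensity units on the EC arrays and from 1062.2 to 1661.0 on the VSMC arrays, and the number of arrays limits the precision. Control spots and spots that the scanner software marked as non-uniform or as population outliers were left out, and spots of 1 probe were averaged. A probe had to be well above background on at least 4 arrays in the EC fits, and on at least 3 in the VSMC and interaction fits, with at least 2 usable values in each group. Each gene was represented by its probe with the highest mean. XIST, TSIX and genes of the Y chromosome were left out of every fit. Where a probe was not well above background on any array of a group, the change is given as "at least N-fold": the mean of the brighter group over the dimmer group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own.

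Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The EC fit held all 12 EC arrays, the VSMC fit all 7 VSMC arrays, and the difference between the cell types' responses to NT30 was the interaction term of a fit to 15 arrays. Cell types were analysed separately, which the design text states. The comparison of both flat groups served as a check of cell identity. A set of 34 gene lists (pathways, cell type markers and complexes) was tested with limma's camera at its preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Every list change below is a median log2 change over measured members. Errors on log2 changes are standard errors from the fit. Groups, tests, gene lists and the rule for named genes were fixed before the data were examined.

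Genes were named by rule. Among genes past the threshold whose treated arrays all lay above or all below the flat arrays, the 12 highest and 12 lowest log2 changes were taken. Each gene list with a camera adjusted p below 0.05 added its 4 members with the smallest p. Where fewer than 10 genes passed, the 10 smallest unadjusted p were taken and are given as not passing. The interaction added its 6 highest and 6 lowest genes, ACTB and GAPDH served as reference genes, and PECAM1, CDH5, VWF, ACTA2, TAGLN, CNN1 and MYH11 checked the cell types. Unnamed or ambiguous genes, HLA genes and genes with common deletions were not named. Probes for metallothioneins, histones, ferritin chains, POU5F1 and FAM72D can also bind near-identical copies or pseudogenes, and their values are uncertain to that extent.

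The EC arrays lay on 3 slides that each held all 3 groups, and the VSMC arrays on 2 slides that each held both groups, so changes were also fitted with slide as a block and computed within each slide. Correlations between arrays of 1 group were 0.958 to 0.990 for EC on flat titanium, 0.984 to 0.990 for EC on NT30, 0.980 to 0.987 for EC on NT100, 0.977 to 0.995 for VSMC on NT30 and 0.989 to 0.995 for VSMC on flat titanium, across probes, and 0 pairs of arrays were identical. As read from the values and not from the labels, EC arrays on NT30 and NT100 of the same number deviated together from their group means (r = 0.145 to 0.635, all 4 pairs above 0.1, as in 1 of the 24 matchings), so the comparison of diameters was also fitted with replicate number as a block. EC on flat titanium replicate 3 had 77% of probes well above background, against 60.5% to 69.7% on the other EC arrays. VSMC on NT30 replicate 1 had 93.1%, against 77.5% to 85.4% on the other VSMC arrays, and 5.68% of its spots were marked as outliers, against at most 0.23% elsewhere among VSMC.

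The procedure was tested on simulated data with 200 changed genes, in equal numbers at true log2 changes of 0.5, 1, 2 and 4. At those sizes it recovered 26%, 76%, 92% and 98% for NT30 against flat in EC (13178 genes), 24%, 78%, 98% and 100% for NT100 against flat, and 32%, 72%, 96% and 98% for NT100 against NT30. For VSMC it recovered 36%, 84%, 88% and 100% (15561 genes), and for the interaction 14%, 54%, 88% and 98% (15938 genes). Unchanged genes made up 5.81%, 5.06%, 2.61%, 2.53% and 3.79% of the calls in these 5 simulations. With 34 lists tested, camera called the 1 list that was moved and 0 others in each simulation. The simulated genes varied independently of each other. These simulations therefore do not test camera where genes of a list are correlated, and most list calls below were lost with an estimated correlation.

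Alternatives were normexp background correction (offset 50) followed by the same scaling, quantile and median scaling, no filter on dim probes, probes well above background on every array, outlier spots kept, every probe tested, the mean over a gene's probes, the authors' deposited log2 values for EC, limma with trend and robust settings, array weights, slide or replicate number as a block, a fit to the 2 groups alone or to all 19 arrays, an adjusted p below 0.01, a log2 change of at least 1, a plain t-test per gene with the same adjustment, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from values computed with numpy 2.4.6.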

Results

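The data comprised 19 expression arrays of human aortic endothelial cells, which line the vessel, and vascular smooth muscle cells, which form its contractile wall, after 24 h on flat titanium or on titanium dioxide nanotubes. The question, as the design states it, was how each cell type responds to the nanotube surface. The 5 groups were EC on flat titanium, NT30 and NT100 (n = 4 arrays each), and VSMC on flat titanium (n = 4) and NT30 (n = 3). Between 60.5% and 77% of probes were well above background on the EC arrays and between 77.5% and 93.1% on the VSMC arrays.

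Cells on flat titanium carried the markers of their type. The mean of the contractile list was 3.88 higher in VSMC than in EC on the log2 scale, and that of the fibroblast and mesenchymal list 8.73 higher. This check parts VSMC from EC and does not tell smooth muscle from fibroblast-like cells. Relative to EC, VSMC had lower PECAM1, the platelet endothelial adhesion molecule (log2 -9.02 ± 0.09), CDH5, the endothelial cadherin (-10.76 ± 0.29), and VWF, the von Willebrand factor (-7.37 ± 0.14). They had higher levels of ACTA2, smooth muscle actin (6.80 ± 0.08), TAGLN, an actin-binding protein of smooth muscle (5.98 ± 0.14), CNN1, calponin (7.12 ± 0.32), and MYH11, smooth muscle myosin heavy chain (3.77 ± 0.46; limma, 4 against 4 arrays, adjusted p from 5.0e-10 to 0.000141). The reference genes differed as well, with GAPDH at 0.97 ± 0.11 and ACTB at -0.68 ± 0.16. In this comparison 10423 of 15219 genes passed, 4420 higher and 6003 lower in VSMC. Cell type coincided with array design and scan, and the median of all genes lay at -0.15, or -0.29 with median scaling and -0.3 with normexp, so these sizes are relative to that shift. With normexp MYH11 stood at 1.0 and ACTB at -0.30, and neither passed (adjusted p = 0.302 and 0.429; lowest 2.68e-06 and 3.13e-06 over their alternatives), and CDH5 stood at -6.51. Of these 10423 calls 42.4% were higher.

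In EC on NT100, 7 genes rose and 4 fell against flat titanium (4 against 4 arrays, 13178 genes tested). The highest were CCR3, the eotaxin receptor (log2 1.95 ± 0.30, 3.87-fold, adjusted p = 0.0413), and CCN3, a secreted matricellular protein (1.81 ± 0.28, 3.51-fold, adjusted p = 0.0395). SLC32A1, the vesicular transporter of inhibitory amino acids, rose by 1.39 ± 0.18, and CLDN14, a tight junction protein, by 1.30 ± 0.16 (adjusted p = 0.0348 for both). CNKSR3, a signalling scaffold (0.82 ± 0.12), MELTF, an iron-binding surface protein (0.74 ± 0.10), and NHSL3 (0.72 ± 0.11) rose less. NRXN3, a neurexin adhesion protein (-1.24 ± 0.18), MEST, an imprinted gene (-1.15 ± 0.16), TAGLN (-0.96 ± 0.14) and UBASH3B, a phosphatase (-0.71 ± 0.10), were lower (adjusted p = 0.0348 or 0.0349). The 5′ to 3′ balance of the RNA, described below, also parted the flat EC arrays (lowest 0.0211) from all nanotube EC arrays (highest 0.00666). Its influence cannot be told apart from that of the surface for any gene or list of EC compared with flat titanium.

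On the scale of log2 signal minus the array's 75th percentile, CLDN14 went from -0.42 ± 0.24 (SD, n = 4) on flat titanium to 0.88 ± 0.28 on NT100, and TAGLN from 0.56 ± 0.29 to -0.40 ± 0.14. The hg17 probe positions were chromosome 21, 36754825 to 36754884, for CLDN14, chromosome 20, 36791242 to 36791301, for SLC32A1, and chromosome 8, 120505616 to 120505675, for CCN3. Those of MEST and TAGLN were chromosome 7, 129739599 to 129739658, and chromosome 11, 116580365 to 116580424. For all 11 genes the NT100 arrays lay wholly apart from the flat arrays, as did 5.66% of all genes tested, where chance gives 2.86%. The changes kept their sizes with slide as a block, for example 1.26 for CLDN14 and -0.97 for TAGLN, but 0 genes passed there in limma (adjusted p from 0.117 to 0.151 for the 11 genes), beside 1214 at an unadjusted p below 0.05 without the block, and 0 passed with each gene's own variance alone. Within slides TAGLN differed by -0.96, -1.23 and -0.62. Leaving out EC on flat titanium replicates 1, 2, 3 and 4 gave 1, 0, 4 and 0 calls, and leaving out NT100 replicates 1, 2, 3 and 4 gave 0, 2, 1 and 0. Median scaling left 100% of calls higher and quantile scaling 83.3%, against 63.6%. With normexp 0 genes passed, and SLC32A1 stood at -0.04, CCN3 at 0.14 and CCR3 at 0.60. With the authors' values SLC32A1 stood at 0.62, CCN3 at 0.72 and UBASH3B at -0.31. These 3 did not pass there (adjusted p = 0.107, 0.107 and 0.247), while CCR3 at 1.15, NRXN3 at -0.78 and MEST at -0.74 did. With the mean over probes MELTF stood at 0.41 and CCN3 at 0.96 (adjusted p = 0.29 and 0.123). With probes well above background on every array CCN3 stood at 0.12 (0.884).

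**Figure D1:**
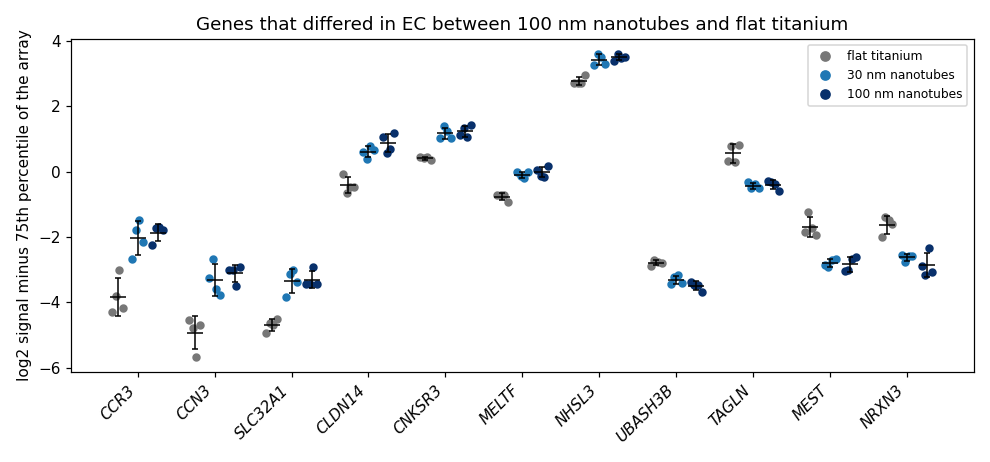
Log2 signal minus the array's 75th percentile (vertical axis) of the 11 genes that passed in EC on 100 nm nanotubes, for each EC array on flat titanium, NT30 and NT100; points are arrays and bars are mean ± SD (n = 4). CLDN14 averaged -0.42 on flat titanium, 0.61 on NT30 and 0.88 on NT100.

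Contractile and cytoskeletal genes were lower as groups in EC on NT100. Of 14 measured smooth muscle contractile genes, TAGLN passed over all genes, 7 were lower when adjusted over the list alone and 12 had a negative change (median -0.334, camera adjusted p = 4.42e-06). This list also passed with an estimated correlation (adjusted p = 0.0242, the highest over its 14 alternatives, lowest 8.84e-07), with slide as a block (median -0.323) and with every array left out, and its mean differed by -0.357, -0.389 and -0.33 within slides. Examples that did not pass were MYL9, the myosin regulatory light chain (-0.77 ± 0.15, adjusted p = 0.121), and PPP1R14A, an inhibitor of myosin phosphatase (-0.70 ± 0.16, adjusted p = 0.16). Among 33 genes of the actin cytoskeleton and its SRF/MRTF regulators, 1 fell over all genes, 6 were lower when adjusted over the list alone and 24 were negative (median -0.145, camera adjusted p = 0.00216, and 0.4 with an estimated correlation). This list shares TAGLN, MYL9, TPM2 and other members with the contractile list, and the 1 gene that fell was TAGLN again. The 2 lists are therefore not separate results. PDLIM7, an actin-binding LIM protein, had -0.57 ± 0.12 (adjusted p = 0.138). Actin genes lost their call without NT100 replicate 2 (adjusted p = 0.0748) and with normexp (0.996, the highest over alternatives; lowest 0.000297). The 5′ to 3′ balance of the RNA, as the difference between 5′ and 3′ probes of 1213 pairs 300 to 1000 bases apart, moved in the same arrays: 0.0425 ± 0.0192 (SD, n = 4) on flat titanium and -0.0213 ± 0.0253 on NT100, a difference of -0.0638 (exact permutation p = 0.0286, the smallest that 70 splits allow; 0.0572 adjusted over 8 tests; -0.0579 with slide as a block, and -0.0771 to -0.0144 within slides).

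All 35 measured genes of G2/M and mitosis and all 30 of G1/S and DNA replication had negative changes on NT100, although 0 passed singly in limma. The G2/M median was -0.873 (adjusted p = 2.35e-09; adjusted p = 0.503 with an estimated correlation, the highest over alternatives, lowest 1.67e-22), with KIF20A, a mitotic kinesin, at -1.22 ± 0.50 (adjusted p = 0.49) and CDC20, an activator of the anaphase-promoting complex, at -1.06 ± 0.52 (adjusted p = 0.564). The mean differed by -1.08, -0.578 and -0.957 within slides. For G1/S the median was -0.381 (adjusted p = 4.73e-05; adjusted p = 0.634 with an estimated correlation), -0.402 with slide as a block, with RFC3, a subunit of the clamp loader, at -0.65 ± 0.31. Within slides its mean differed by -0.565, -0.131 and -0.799. Both calls held with each array left out.

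Immediate early genes, transcription factors induced within minutes of a stimulus, had higher values as a group on NT100 (22 measured, 6 higher when adjusted over the list alone, 15 positive, median 0.113, mean 0.538, adjusted p = 8.11e-05; adjusted p = 0.184 with an estimated correlation). FOSB stood at 2.43 ± 0.52 (adjusted p = 0.142), ATF3 at 2.23 ± 0.45 (0.138) and EGR1 at 1.36 ± 0.24 (0.0848), none of which passed over all genes. Oxidative stress genes of the NRF2 pathway were higher (27 measured, 4 when adjusted over the list alone, median 0.119, adjusted p = 0.000246; adjusted p = 0.428 with an estimated correlation), with HMOX1, heme oxygenase, at 0.64 ± 0.19, GPX3, the secreted glutathione peroxidase, at 0.66 ± 0.14 and FTL, the ferritin light chain, at 0.45 ± 0.13. Lysosome and autophagy genes (28 measured, median 0.124, adjusted p = 0.00143), unfolded protein response genes (28, 0.13, 0.00206) and matrix proteases (20, 0.195, 0.00323) were higher too, with adjusted p = 0.428, 0.428 and 0.24 with an estimated correlation. ADAMTS1, a matrix protease, had 1.08 ± 0.35 (adjusted p = 0.372). These 5 lists kept their calls with every array left out. The cholesterol biosynthesis list (27 measured, median 0.205, adjusted p = 0.00193; adjusted p = 0.634 with an estimated correlation) lost its call without NT100 replicate 4 (adjusted p = 0.258), and its mean differed by 0.213, 0.488 and -0.192 within slides.

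Another 5 lists stood nearer the threshold on NT100. Flow-responsive KLF2/KLF4 genes (median 0.266, adjusted p = 0.0135), replication-dependent histones (0.338, 0.021) and vasoactive genes (0.146, 0.0423) were higher, and oxidative phosphorylation (-0.112, 0.0376; higher with normexp, adjusted p = 0.0442) and TGF-beta and BMP targets (-0.151, 0.0376) were lower. With an estimated correlation their adjusted p = 0.268 to 0.634. Vasoactive genes lost their call whichever array was left out (adjusted p from 0.0521 to 0.3), with EDNRB, an endothelin receptor, at 0.73 ± 0.16 (adjusted p = 0.16) and ACE, the angiotensin-converting enzyme, at -0.86 ± 0.25 (0.312). The other 4 lost theirs in 2 to 5 of the 8 fits that left out 1 array, NT100 replicates 1 to 4 and flat replicates 1, 2 and 4 among them. KLF4, a transcription factor induced by flow, had 0.91 ± 0.31. GAPDH differed by 0.02 ± 0.10 and ACTB by 0.20 ± 0.20, which did not pass, and both changed sign with the authors' deposited values.

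In EC on NT30, 0 of 13178 genes passed against flat titanium in limma (smallest adjusted p = 0.0793), beside 877 at an unadjusted p below 0.05, 0 with each gene's own variance alone and 0 with slide as a block. The genes with the smallest p, none of which passed, were largely those named on NT100: SLC32A1 at 1.36 ± 0.18, TAGLN at -0.98 ± 0.14 and MEST at -1.11 ± 0.16 (adjusted p = 0.0793), CNKSR3 at 0.76 ± 0.12, MELTF at 0.67 ± 0.10, CLDN14 at 1.02 ± 0.16 and MYL9 at -0.90 ± 0.15 (adjusted p = 0.0922 to 0.0995). CCR3 had 1.80 ± 0.30, CCN3 1.61 ± 0.28 and NHSL3 0.65 ± 0.11. With normexp SLC32A1 and CCN3 changed sign (-0.06 and -0.01) and CCR3 stood at 0.48. In this comparison 4.85% of genes had NT30 arrays wholly apart from flat arrays, where chance gives 2.86%. Leaving out EC on flat titanium replicate 3 gave 6 calls, leaving out NT30 replicate 1 gave 1, and leaving out any other array gave 0. Median scaling gave 1 call, higher, and quantile scaling 9, of which 77.8% were higher.

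Contractile and cytoskeletal genes, whose lists share members, were lower as groups on NT30 as well. Contractile genes (14 measured, 0 past the threshold over all genes, 4 lower when adjusted over the list alone, 13 negative, median -0.384, adjusted p = 1.35e-08) passed also with an estimated correlation (adjusted p = 0.00603, the highest over its 14 alternatives, lowest 6.41e-10) and with slide as a block (median -0.334), and the mean differed by -0.311, -0.495 and -0.392 within slides. TPM2, a tropomyosin, had -0.47 ± 0.13, PPP1R14A -0.64 ± 0.16 and PDLIM7 -0.61 ± 0.12. Actin cytoskeleton genes were lower as well (33 measured, 6 when adjusted over the list alone, 24 negative, median -0.224, adjusted p = 1.3e-06; adjusted p = 0.15 with an estimated correlation; 0.489 with normexp, the highest over alternatives, lowest 2.15e-07), with within-slide means of -0.223, -0.26 and -0.143. CFL1, cofilin, had -0.52 ± 0.13 (adjusted p = 0.392). The 5′ to 3′ balance differed here too, at -0.0185 ± 0.0231 (SD, n = 4) on NT30, -0.0611 below flat titanium (exact permutation p = 0.0286, the smallest possible; -0.0579 with slide as a block, and -0.0725 to -0.0438 within slides). Immediate early genes were higher (22 measured, 6 when adjusted over the list alone, median 0.117, adjusted p = 0.000554; adjusted p = 0.204 with an estimated correlation), with FOS at 1.84 ± 0.51, FOSB at 2.23 ± 0.52, ATF3 at 1.98 ± 0.45 and EGR1 at 1.1 ± 0.24. These 3 lists kept their calls with every array left out.

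**Figure D2:**
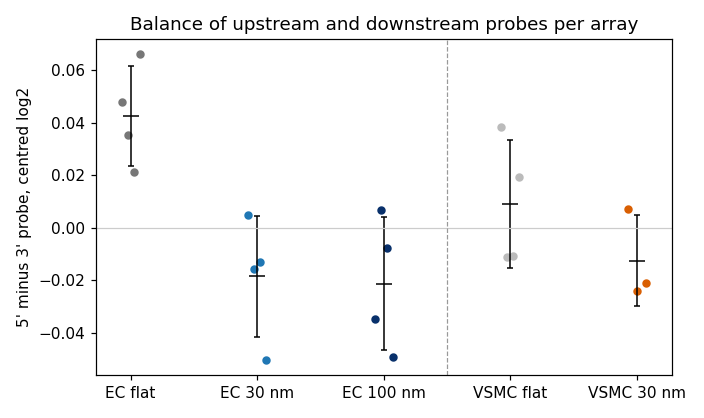
Median over probe pairs of the difference in log2 signal between the 5′ and the 3′ probe of a gene, centred over arrays (vertical axis), for each array of the 5 groups. Pairs lay 300 to 1000 bases apart, points are arrays and bars are mean ± SD. EC averaged 0.0425 on flat titanium, -0.0185 on NT30 and -0.0213 on NT100.

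Cell division genes on NT30 varied with slide and array. All 35 G2/M genes were negative (median -0.566, adjusted p = 5.5e-05; adjusted p = 0.674 with an estimated correlation), yet the mean differed by -1.4 and -1.13 on slides 1 and 2 and by 0.407 on slide 3, with a median of -0.654 with slide as a block. KIF20A had -0.85 ± 0.50 (adjusted p = 0.824) and TPX2, a spindle assembly factor, -0.62 ± 0.42 (0.866). The call was lost without EC on flat titanium replicate 1 (adjusted p = 0.203) or NT30 replicate 2 (0.187), with 4.17e-16 to 0.726 over its alternatives. G1/S genes were negative in 29 of 30 (median -0.199, adjusted p = 0.0139; adjusted p = 0.816 with an estimated correlation), with -0.948, -0.408 and 0.2 within slides, and lost their call without flat replicate 1 (0.696) or NT30 replicates 2 (0.88) or 3 (0.175).

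A further 6 lists passed on NT30. TGF-beta and BMP targets were lower (27 measured, 1 when adjusted over the list alone, median -0.217, adjusted p = 0.00506; adjusted p = 0.403 with an estimated correlation; 0.093 without NT30 replicate 1, from 6.66e-05 to 0.403 over alternatives), with ENG, a TGF-beta co-receptor of endothelium, at -0.83 ± 0.15 (adjusted p = 0.126) and ID3, a BMP target, at -0.57 ± 0.25. NRF2 genes were higher (27 measured, median 0.0914, adjusted p = 0.00683; adjusted p = 0.611 with an estimated correlation), with HMOX1 at 0.66 ± 0.19 and FTH1, the ferritin heavy chain, at 0.33 ± 0.13, but not without flat replicate 3 (0.0876) or NT30 replicate 3 (0.0723). Histones (median 0.294, adjusted p = 0.00996), unfolded protein response genes (0.124, 0.00996), KLF2/KLF4 genes (0.0914, 0.0139) and lysosome genes (0.134, 0.0224) were higher, with adjusted p = 0.403, 0.54, 0.54 and 0.62 with an estimated correlation. Histones lost their call without NT30 replicate 3 (0.115), unfolded protein response genes without flat replicate 3 (0.183), KLF2/KLF4 genes without flat replicate 1 (0.0933) or NT30 replicate 2 (0.22), and lysosome genes without flat replicate 3 (0.259) or NT30 replicates 2 (0.271) or 3 (0.0723).

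Markers of other cells and stress lists stood near the threshold on NT30. The fibroblast and mesenchymal list had 6 of 7 measured genes positive (median 0.396, adjusted p = 0.0409; adjusted p = 0.334 with an estimated correlation; 0.211 with slide as a block), with COL1A2, a collagen chain, at 0.49 ± 0.38 and S100A4 at 0.76 ± 0.51, and its direction changed with normexp (0.991). NF-kB cytokine and adhesion genes (median 0.182, adjusted p = 0.0338), interferon-stimulated genes (0.0547, 0.0373), matrix proteases (0.171, 0.0373) and, in the other direction, oxidative phosphorylation (-0.0935, 0.0328; higher with normexp, adjusted p = 0.0152) had adjusted p = 0.403 to 0.674 with an estimated correlation. CCL2, a monocyte chemokine, had 0.81 ± 0.27 (adjusted p = 0.57). OASL, an interferon-induced gene not well above background on flat titanium, had a value of at least 1.64-fold on NT30 (adjusted p = 0.43). OASL did not pass and stood at a log2 change of -0.1455 with normexp, so a rise was not shown. These 5 lists lost their calls in 3 to 6 of the 8 fits that left out 1 array, and each of the 8 arrays ended at least 1 of the calls. Over all lists, 16 passed, against 9 without flat replicate 1, 9 without NT30 replicate 3 and 10 without NT30 replicate 2. The endothelial identity list did not pass (25 measured, median 0.000105, adjusted p = 0.919). ACTB (0.11 ± 0.20) and GAPDH (-0.04 ± 0.10) did not pass, and their signs changed with quantile scaling and with normexp, respectively.

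Between the pore diameters no gene passed in EC: 0 of 13178 genes differed between NT100 and NT30 in limma (smallest adjusted p = 1), beside 54 at an unadjusted p below 0.05 and 0 with each gene's own variance alone. All 35 splits of these arrays gave at least 54 genes at that unadjusted p. In this comparison 0.319% of genes had NT100 arrays wholly apart from NT30 arrays, where chance gives 2.86%. Both counts lay below chance, so the 0 calls do not show that the diameters act alike. Differences with the smallest p, which did not pass, were ZNF20 at 0.52 ± 0.17, TSACC at -0.37 ± 0.12 and NEAT1, a nuclear long non-coding RNA, at -0.67 ± 0.22. RNASE7 was not well above background on NT100. All 11 genes that passed on NT100 had the same sign on NT30, an unadjusted p below 0.05 there and NT30 arrays apart from flat arrays, and 0 of the 11 differed between the diameters at an unadjusted p below 0.05. These genes had been chosen by their difference from the same flat arrays, with the same estimate of spread. Their change on NT30 is therefore not separate support. Across genes, which are not independent replicates, the NT30 and NT100 changes correlated at r = 0.845, where unchanged groups against the same flat arrays gave 0.5 (0.455 to 0.529 in 100 simulations of independent arrays), and at 0.328 with the flat arrays split between the comparisons (0.221 to 0.477 over 6 splits). NT30 and NT100 arrays of the same number also deviated together (r = 0.145 to 0.635 over 4 pairs), which the simulations leave out. The simulated genes also varied independently of each other. The simulated range is therefore too narrow for genes that move together, and does not show how far 0.845 lies from chance. With neither flat arrays nor numbers shared, an alternative chosen after seeing the data, the correlation was 0.232 (-0.0246 to 0.436 over 6 splits). Their covariance was 0.0621 against 0.0265 in the simulations, 0.033 with split flat arrays and 0.0281 (-0.00342 to 0.0536) with numbers split as well.

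Several lists differed between the diameters at the preset correlation only. All 35 G2/M genes were lower on NT100 than on NT30 (median -0.322, adjusted p = 8.3e-06; adjusted p = 0.838 with an estimated correlation), with -0.244 with slide as a block and 0.323, 0.549 and -1.36 within slides, and TTK, a spindle checkpoint kinase, at -0.57 ± 0.56. The call was lost without NT30 replicate 1 (adjusted p = 0.0658, with the opposite direction), NT100 replicate 2 (0.107) or NT100 replicate 4 (0.0952). G1/S genes had a median of -0.171 (adjusted p = 0.000562; adjusted p = 0.838 with an estimated correlation), lost without the same 3 arrays (0.113, 0.516 and 0.0791). Cholesterol biosynthesis genes were higher in 25 of 27 (median 0.147, adjusted p = 8.3e-06; adjusted p = 0.838 with an estimated correlation), with within-slide means of 0.4, 0.249 and -0.354, and lost their call without NT30 replicate 2 (0.0882) or NT100 replicate 4 (0.831). HMGCS1, an enzyme early in that pathway, had 0.32 ± 0.26. Interferon-stimulated genes (-0.0818, adjusted p = 0.00779), actin cytoskeleton genes (0.0774, 0.00906), NRF2 genes (0.0654, 0.0389), vasoactive genes (0.0775, 0.0407), hypoxia and glycolysis genes (0.0486, 0.0407) and lysosome genes (0.0497, 0.0445) had adjusted p = 0.657 to 0.838 with an estimated correlation, and each lost its call in 4 to 8 of the 8 fits that left out 1 array. With replicate number as a block in a fit to these 8 arrays, hypoxia and lysosome genes did not pass (adjusted p = 0.0562 and 0.0568). Of the 9 lists, 5 passed with slide as a block, 2 without NT30 replicate 1, 4 without NT100 replicate 2, 5 without replicate 3 and 4 without replicate 4. ACTB differed by 0.10 ± 0.20, with the opposite sign under quantile scaling, and GAPDH by 0.07 ± 0.10.

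In VSMC on NT30, 991 of 15561 genes passed against flat titanium, 484 higher and 507 lower (3 against 4 arrays). None passed with replicate number as a block, although the values did not show these arrays to be paired by number. Among the higher genes, NR4A2 and NR4A1, orphan nuclear receptors of the immediate early class, rose by 1.68 ± 0.18 and 1.40 ± 0.16 (adjusted p = 0.00591 and 0.00714), HAS1, a hyaluronan synthase, by 1.58 ± 0.14 (adjusted p = 0.00275), and the bradykinin receptors BDKRB1 and BDKRB2 by 1.33 ± 0.11 and 1.16 ± 0.11 (adjusted p = 0.00192 and 0.00398). DHRS9, a short-chain dehydrogenase (1.52 ± 0.11), ZC3H7B, a zinc finger protein (1.32 ± 0.10), and HYCC2 (1.20 ± 0.16) rose too. Among the lower genes, TMED9, a cargo protein of the early secretory pathway, fell by 3.27 ± 0.16 (9.63-fold, adjusted p = 0.000327), EML2, a microtubule-associated protein, by 3.19 ± 0.26, and PRKAG1, a subunit of AMP-activated kinase, by 2.79 ± 0.15. PIP5K1A, a phosphoinositide kinase (-2.44 ± 0.12), WLS, which carries Wnt proteins to the surface (-2.54 ± 0.26), TAF5L, a subunit of a histone acetyltransferase complex (-2.60 ± 0.31), and RTL5 (-2.67 ± 0.07, adjusted p = 9.19e-05) fell as well. With the mean over a gene's probes PIP5K1A stood at -1.24, TAF5L at -1.13 and NR4A1 at 0.84. None of these 3 passed there (adjusted p = 0.0602, 0.0697 and 0.0741; lowest 5.67e-07, 0.000281 and 0.000177 over their alternatives).

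TMED9 went from 4.26 ± 0.14 (SD, n = 4) to 0.99 ± 0.33 (n = 3) in log2 units relative to the 75th percentile, and HAS1 from -3.77 ± 0.13 to -2.18 ± 0.28. Probe positions on hg17 were chromosome 5, 176954998 to 176955057, for TMED9, chromosome 19, 56911396 to 56912034, for HAS1, chromosome 14, 95800764 to 95800823, for BDKRB1 and 95780094 to 95780153 for BDKRB2, and X, 71130538 to 71131050, for RTL5. Lower genes had larger changes: 141 genes were lower and 18 higher by at least 1 on the log2 scale. Other probes of those 141 genes often moved less: over 21 pairs in 15 genes with a probe more than 3 kb away, the median share of the change at the other probe was 0.202, against 0.537 over 30 pairs 300 to 3000 bases apart and 0.957 over 4 pairs within 300 bases. For genes lower by under 1 it was 0.286 over 84 pairs more than 3 kb apart, and for higher genes 0.678 over 131. Dim genes were less certain. TNN, TMPRSS15, DNAI2, TUBB1 and C1QL2 passed at -2.59 ± 0.23, -2.79 ± 0.30, -2.64 ± 0.43, -2.58 ± 0.40 and -2.44 ± 0.41 with only 2 usable NT30 arrays, and stood at -0.48, -0.86, -0.35, -0.08 and -0.63 with outlier spots kept (adjusted p from 0.763 to 0.987). GALP, the galanin-like peptide, not well above background on flat titanium, passed on 2 usable NT30 arrays (adjusted p = 0.0182), at least 5.4-fold higher there. Its size is uncertain, since it stood at a log2 change of 0.07 with normexp (adjusted p = 0.956). CXCL6, a neutrophil chemokine (1.18 ± 0.21), SPMAP2 (1.17 ± 0.20) and FOXC2, a forkhead transcription factor (1.15 ± 0.25), passed at adjusted p = 0.0293, 0.0254 and 0.0485. With slide as a block these 3 genes had adjusted p = 0.0597, 0.0501 and 0.0871, and SPMAP2 stood at -0.15 with normexp.

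All 991 genes had NT30 arrays wholly apart from flat arrays, as did 26.6% of all genes tested, where chance gives 5.71%. With slide as a block 487 genes passed (198 higher and 289 lower), 474 of them among the 991. Of 33 named genes that passed, 19 kept their call with each of the 7 arrays left out, and TNN and TMPRSS15 in the 5 fits that their usable arrays allowed. No gene passed with replicate number as a block, and each of the 33 lost its call under at least 1 alternative. MT1A and MT1H lost it whichever array was left out. GALP, CXCL6, SPMAP2, FOXC2, DNAI2, TUBB1, C1QL2, ATP5MC1, MTF1 and PCNA lost it without at least 1, VSMC on flat titanium replicate 4 in each case (adjusted p up to 0.134 over the arrays left out). The count was 492 without NT30 replicate 1, 381 without NT30 replicate 2, and 239, 341 and 238 without flat replicates 2, 3 and 4. NT30 replicate 1 is the array with 93.1% of probes well above background. Higher genes made up 48.8% of the calls, 26.9% with median scaling, 29.9% with quantile scaling and 8.11% with normexp, which left 148 calls and put the median of all genes at -0.15. Among others, DHRS9, HAS1, NR4A2, ZC3H7B, HYCC2, BUB1 and TAF5L no longer passed with normexp (adjusted p from 0.0628 to 0.683; lowest 2.83e-05 for ZC3H7B over its alternatives). HAS1 stood there at 0.76, DHRS9 at 0.67, NR4A2 at 0.37, HYCC2 at 0.22, BUB1 at 0.55, ZC3H7B at 0.83 and TAF5L at -1.62.

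**Figure D3:**
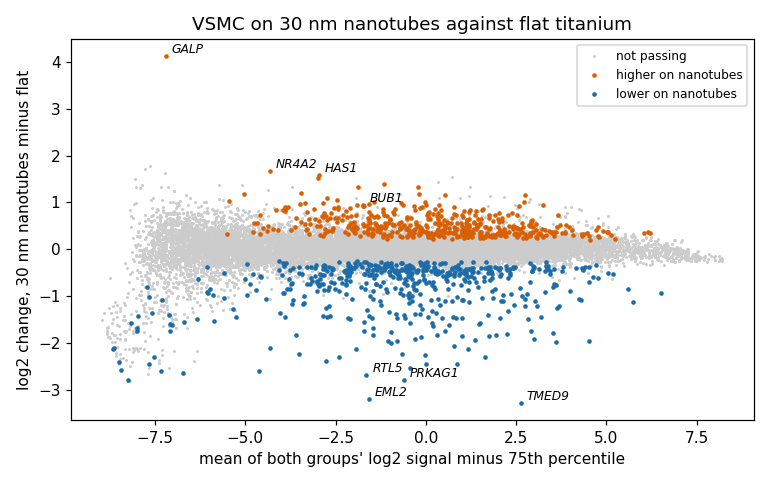
Log2 change of each gene in VSMC on 30 nm nanotubes against flat titanium (vertical axis) over its mean log2 level relative to the 75th percentile (horizontal axis); coloured points are the 484 genes that passed as higher and the 507 as lower, with median scaling giving 26.9% higher instead of 48.8%. TMED9 lies lowest at -3.27.

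Mitotic genes rose together in VSMC on NT30. Of 35 measured G2/M genes, 26 rose over all genes, 33 were higher when adjusted over the list alone and 0 fell (median 0.682, adjusted p = 3.37e-18; adjusted p = 0.961 with an estimated correlation, the highest over alternatives, lowest 3.41e-30). BUB1, a spindle checkpoint kinase, rose by 0.95 ± 0.12, DLGAP5, a spindle protein, by 0.89 ± 0.11, HMMR, a hyaluronan-binding spindle protein, by 0.84 ± 0.11, and CCNB1, the mitotic cyclin, by 0.82 ± 0.10 (adjusted p = 0.00906 to 0.0109). The median was 0.699 with slide as a block, and the mean differed by 0.58 and 0.857 within slides. The call held with every array left out. G1/S genes were higher in 25 of 30 (1 rose over all genes, 3 when adjusted over the list alone, median 0.207, adjusted p = 0.00138; adjusted p = 0.961 with an estimated correlation), with PCNA, the replication clamp, at 0.35 ± 0.07 (adjusted p = 0.0365) and RRM1, a ribonucleotide reductase subunit, at 0.28 ± 0.07, which did not pass. Within slides the G1/S mean differed by 0.141 and 0.442, and the call was lost without NT30 replicate 2 (adjusted p = 0.106).

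Metallothioneins and metal response genes were higher in 12 of 13 (3 rose over all genes, 4 when adjusted over the list alone, median 0.284, adjusted p = 0.00138; adjusted p = 0.961 with an estimated correlation), with within-slide means of 0.275 and 0.279. MTF1, the metal-responsive transcription factor, rose by 0.34 ± 0.06, and the metal-binding MT1A and MT1H by 0.37 ± 0.08 and 0.35 ± 0.08 (adjusted p = 0.0495 and 0.0468), while MT1X at 0.27 ± 0.07 did not pass. Cholesterol biosynthesis genes (28 measured, 0 over all genes, 7 higher and 1 lower when adjusted over the list alone, median 0.184) and oxidative phosphorylation genes (25 measured, 1 rose over all genes, 6 when adjusted over the list alone, median 0.139) were higher, both with an adjusted p = 0.00677 and an adjusted p = 0.961 with an estimated correlation. ATP5MC1, a subunit of ATP synthase, rose by 0.37 ± 0.06 (adjusted p = 0.0176), while CYP51A1 at 0.34 ± 0.08 and LSS at -0.25 ± 0.07, both of sterol synthesis, did not pass. Both lists lost their calls without NT30 replicate 2 (adjusted p = 0.102 and 0.127). Within slides their means differed by 0.124 and 0.236, and by 0.139 and 0.186. Contractile genes did not pass as a list (18 measured, 1 fell, median -0.075, adjusted p = 0.26), nor did NF-kB genes (28 measured, 6 rose, 1 fell, median 0.086, adjusted p = 0.332). ACTB (-0.20 ± 0.11) and GAPDH (-0.19 ± 0.11) did not pass. In all 5 lists passed, against 9 without NT30 replicate 3 and 9 without flat replicate 1. The 5′ to 3′ balance differed by -0.0214 over 1470 pairs 300 to 1000 bases apart and by 0.00342 over 2166 pairs 1000 to 3000 bases apart (exact permutation p = 0.257 and 0.886).

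The change on NT30 differed between the cell types for 173 of 15938 genes, 51 more positive and 122 more negative in VSMC (15 arrays, interaction term). Cell type coincided with array design and scan. Median raw signal was 1.78 to 2.79 times that of negative controls on EC arrays and 7.3 to 11.89 times on VSMC arrays. An influence of design or scan on the size of changes would not cancel in this term and was not tested. With each cell type's change taken from its own fit, HMOX1 had 0.66 ± 0.19 in EC and -1.06 ± 0.11 in VSMC, with an interaction of -1.72 ± 0.21 (adjusted p = 0.00284). ATF3, a stress-induced transcription factor, had 1.98 ± 0.45 and -0.35 ± 0.09 (difference -2.32 ± 0.39, adjusted p = 0.015). TMED9 (-3.15 ± 0.34), EML2 (-2.85 ± 0.34), SLC39A7, a zinc transporter of the endoplasmic reticulum (-2.43 ± 0.25), and AQP3, an aquaglyceroporin (-2.79 ± 0.38), were more negative in VSMC (adjusted p = 0.0012 to 0.00514). These 6 genes kept their calls with each of the 15 arrays left out, but each lost its call under at least 1 other alternative. No gene passed with replicate number as a block. TAGLN was the reverse, at -0.98 ± 0.14 in EC and -0.12 ± 0.08 in VSMC (difference 0.86 ± 0.18, adjusted p = 0.0419), as was MEST at -1.11 ± 0.16 and -0.08 ± 0.12 (1.03 ± 0.21, adjusted p = 0.0368).

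Other genes that differed were GRB14, a receptor adapter (1.04 ± 0.18), BMP6, a bone morphogenetic protein (0.99 ± 0.19), HYCC2 (1.27 ± 0.24), FAM72D (1.12 ± 0.23), PRKAG1 (-2.48 ± 0.43), GPX3 (-1.0 ± 0.17), DDIT4, an inhibitor of mTOR signalling (-1.17 ± 0.21), and POU5F1 (-2.40 ± 0.29), with adjusted p from 0.00374 to 0.0419. GALP, dim on flat titanium in VSMC, had a fitted difference of 4.35 ± 0.91 that is no bound (adjusted p = 0.0491) and stood at 0.86 with normexp. HYCC2 at 0.54, BMP6 at 0.56, GPX3 at -0.51 and AQP3 at -1.59 were smaller there as well. None of these 5 passed with normexp (adjusted p = 1; lowest 0.000158 for AQP3 over its alternatives). With slide as a block TAGLN, PRKAG1, GPX3, DDIT4, HYCC2, BMP6 and FAM72D had adjusted p = 0.0522 to 0.0861. POU5F1 stood at -0.73 without VSMC on NT30 replicate 2 (adjusted p = 0.344) and at -0.46 without replicate 3 (0.49), and did not pass there, and GPX3 and GRB14 without replicate 1 (0.0569 and 0.055). With each of 15 arrays left out, PRKAG1 kept its call 13 times, DDIT4 11, HYCC2 10, BMP6 9, MEST and FAM72D 5 and TAGLN 3, and GALP kept its call in 3 of 13 fits.

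With slide as a block 128 genes passed, and without both arrays that stood apart, an alternative chosen after seeing the data, 143. The count was 96 without EC on flat titanium replicate 2, 290 and 108 without EC on NT30 replicates 1 and 3, 83 and 87 without VSMC on NT30 replicates 1 and 3, and 83, 100 and 94 without VSMC on flat titanium replicates 2, 3 and 4. Genes more positive in VSMC made up 29.5% of calls, 3.7% with median scaling, 16.4% with quantile scaling and 0% with normexp.

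Gene groups differed in both directions. G2/M genes were more positive in VSMC in 35 of 35 (median 1.24, adjusted p = 5.0e-09; adjusted p = 0.699 with an estimated correlation), 1.4 with slide as a block, with MKI67, the proliferation antigen, at 1.42 ± 0.56 and ANLN, anillin, at 1.61 ± 0.59, neither of which passed. The G1/S list followed (median 0.399, adjusted p = 0.00346; adjusted p = 0.837 with an estimated correlation), with PCNA at 0.50 ± 0.23, but not without EC on flat titanium replicate 1 (0.111), EC on NT30 replicate 2 (0.174) or VSMC on NT30 replicate 2 (0.0637). Lysosome genes, at a median of -0.197 (adjusted p = 0.000161), with PSAP, prosaposin, at -0.63 ± 0.15, and oxidative phosphorylation genes, at 0.187 (0.000183), with NDUFA1, a subunit of complex I, at 0.40 ± 0.11, held with each array left out but had adjusted p = 0.601 with an estimated correlation. The latter did not pass with normexp (0.34, from 1.69e-06 to 0.601 over alternatives).

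The remaining 5 lists were less certain. NRF2 genes were more negative in VSMC (27 measured, 2 over all genes, 3 when adjusted over the list alone, median -0.132, adjusted p = 0.0128; adjusted p = 0.699 with an estimated correlation), but not without EC on flat titanium replicate 3 (0.148), EC on NT30 replicate 3 (0.0639) or VSMC on NT30 replicate 1 (0.0534). Immediate early genes (26 measured, 1 over all genes, 4 when adjusted over the list alone, median -0.244, adjusted p = 0.0128) lost their call without EC on flat titanium replicate 3 (0.0639), and unfolded protein response genes (28 measured, 2 over all genes, median -0.164, adjusted p = 0.0181) without the same array (0.194) or VSMC on NT30 replicate 1 (0.103). Contractile genes were more positive in VSMC in 16 of 18 (1 over all genes, 3 higher and 1 lower when adjusted over the list alone, median 0.278, adjusted p = 0.0253), with MYL9 at 0.61 ± 0.18, and lost their call without EC on flat titanium replicate 4 (0.0505), VSMC on NT30 replicate 2 (0.222) or VSMC on flat titanium replicate 1 (0.0518). Those 3 lists had adjusted p = 0.601 with an estimated correlation. Extracellular matrix genes (44 measured, median -0.133, adjusted p = 0.0456; adjusted p = 0.699 with an estimated correlation), with P4HA2, a collagen hydroxylase, at -0.53 ± 0.12, kept their call in 8 of the 15 fits that left out an array. ACTB (-0.31 ± 0.21) and GAPDH (-0.15 ± 0.16) did not pass, and GAPDH changed sign without the arrays that stood apart.

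**Figure D4:**
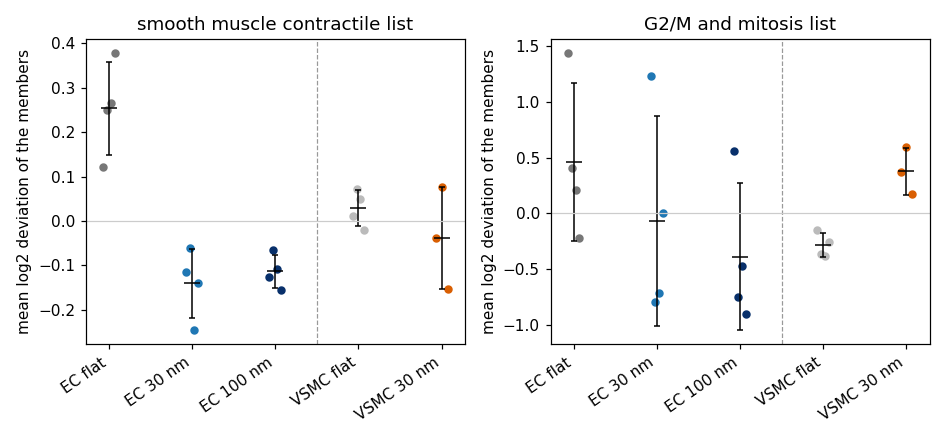
Mean log2 deviation of the members of the smooth muscle contractile and the G2/M and mitosis lists (vertical axis) for each array of the 5 groups; points are arrays, bars are mean ± SD, and the dashed line parts the cell types, which were centred separately. In VSMC the G2/M mean was 0.665 higher on NT30 than on flat titanium.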

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

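Of the tests below, those of the slide for the contractile list, of scaling for the G2/M list, and of distant probes, upstream probes and RNA balance for the genes lower in VSMC were chosen after the results were seen.

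The smooth muscle contractile list was lower in EC on NT30, at a median of -0.384 over 14 genes. For smooth muscle or mesenchymal cells among the flat EC cultures, the 100 other genes with the highest VSMC over EC ratio had a median of 0.142 (SE 0.0455). Loss of such cells would lower these genes, and 37 of them were lower. That ratio used the same flat EC arrays as the change, and choosing genes low on them raises the change by an amount not measured. The presence of such cells therefore stays open. The slide is argued against as the whole cause, since the median was -0.334 with slide as a block. The 5′ to 3′ balance of the RNA, which differed in the same arrays, stays open: over 7 members with 2 or more probes the 3′-most probes had a median of -0.248, the 5′-most -0.286 and the named probes -0.311, and the 5′ probe fell more in only 3, but 7 members are too few to exclude it (median of 5′ minus 3′ change 0.011, SE 0.0608) and every flat array differs from every NT30 array in the balance. A response of EC to the nanotubes therefore remains a hypothesis beside such cells and the RNA balance. The response and the balance cannot be told apart here because the balance follows the groups.

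The G2/M and mitosis list was lower in EC and higher in VSMC on NT30, with a difference of 1.19 in the mean over 35 genes. The arrays that stood apart are argued against, since the median difference was 1.33 without both, and so is scaling, since its lowest value over the scalings was 1.01. Spread between arrays in the share of dividing cells may account for it: an exact relabelling of the arrays within each cell type gave a difference as large with p = 0.0661 over 2450 relabellings. The SD of the array means was 0.704 in EC on flat titanium and 0.937 in EC on NT30, against 0.107 and 0.21 in VSMC on flat titanium and NT30. A different effect of NT30 on division in the 2 cell types was therefore not separable from array spread, most of it among the EC arrays.

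In VSMC on NT30, 141 genes were lower by at least 1 on the log2 scale (median -1.46). VSMC on NT30 replicate 1 is argued against as the whole source, since 133 of the 141 still passed without it. Its spots marked as outliers (5.68%) were already left out, so this does not test genes without a usable value on that array. TNN, TMPRSS15, DNAI2, TUBB1 and C1QL2, which lacked a usable NT30 array, did not pass with outlier spots kept. Loss of 5′ ends would give an upstream probe at least all of the change. For the 32 genes with a probe over 300 bases upstream its median share was 0.376 (SE 0.101, 43 pairs, 11 at 1 or more). The test cannot decide, because choosing genes by the fall of their named probe lowers the share. The upstream share was also below 1 for higher genes (0.721, SE 0.0689) and genes lower by under 1 (0.676, SE 0.0977). A change of only part of the transcript is consistent with the other probes of these genes: over 21 pairs in 15 genes more than 3 kb apart, the other probe showed a median share of 0.202 (SE 0.102) of the change, against 0.537 over 30 pairs 300 to 3000 bases apart and 0.957 over 4 within 300 bases, but the share was also low for genes lower by under 1 (0.286, 84 pairs), unlike genes that rose (0.678, 131 pairs). For genes without such an upstream probe the balance of the RNA stays open too, because no upstream probe tests them. Its difference over all genes did not pass (-0.0214 with exact permutation p = 0.257 and, at 1000 to 3000 bases, 0.00342 with p = 0.886). Switches of transcript end, cross-hybridising probes and a regulated change remain hypotheses that these arrays do not separate, and no biological explanation was tested.

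Other splits of the arrays were used to ask whether any division of the same arrays gives counts as large, with the real split included. By a share of splits under 0.05, chance was argued against for the 991 genes in VSMC (1 of 35 splits as large, highest other 1). The same held for the 173 genes of the interaction (1 of 100 drawn, highest other 92) and the 10423 genes between cell types (1 of 35, highest other 0). In EC on NT100 the real split, with 11 genes, gave the most as well (1 of 35, highest other 0). A share of 1 of 35 is the smallest that 35 splits allow. With slide as a block 0 genes passed in EC on NT100, and 7 of the 11 lost their call whichever array was left out. Chance was therefore not excluded for these 11 genes. For the 16 and 15 lists in EC on NT30 and NT100 the real split also gave the most (1 of 35 each). Another split gave 14 lists in each comparison, and both comparisons share the flat arrays, so chance was not excluded there. It could not be excluded for the 877 genes at an unadjusted p below 0.05 in EC on NT30 (7 of 35, highest other 1799), the 54 such genes between the pore diameters (35 of 35, highest other 2514), the 9 lists between the diameters (12 of 35, highest other 14), the 5 lists in VSMC (30 of 35, highest other 11) or the 9 lists of the interaction (35 of 100, highest other 15). A split of the nanotube EC arrays by replicates 1 and 2 against 3 and 4 gave 287 genes, where the real split gave 0, which points to a structure of the samples. The splits most uneven over slides gave 0 genes past the threshold where the real ones gave 11, 991 and 173. At an unadjusted p below 0.05 they gave 1418 and 1799 genes for EC on flat titanium and NT30, the latter with flat replicates 1, 2 and 4 and NT30 replicate 2 against the rest, while the real split had 948 with slide as a block. Between the diameters they gave 234 and 749 such genes, against 52 with slide as a block, and 10 lists in 1 of 2 splits, against 5 with that block. In VSMC the most uneven split (flat replicates 1 and 3 with NT30 replicate 2) gave 7 lists, as many as the real split with slide as a block. Among the 8 splits between the diameters that part all 4 same-number pairs, the others gave 83 to 868 such genes and 3 to 9 lists, and splits that part fewer gave up to 2514 and 14.

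The difference between the cell types' NT30 changes was tested by the interaction term and passed for 173 genes, with array design and scan coinciding with cell type. In log2 units it was -2.43 for SLC39A7, -3.15 for TMED9, -2.85 for EML2, -1.72 for HMOX1, -2.40 for POU5F1, -2.79 for AQP3, -2.32 for ATF3, -2.48 for PRKAG1, -1.0 for GPX3 and -1.17 for DDIT4. It was positive at 1.04 for GRB14, 1.27 for HYCC2, 0.99 for BMP6, 1.03 for MEST, 0.86 for TAGLN, 1.12 for FAM72D and 4.35 for GALP. Median differences over lists were 1.24 for G2/M, 0.399 for G1/S, 0.278 for contractile genes, 0.187 for oxidative phosphorylation, -0.244 for immediate early genes, -0.197 for lysosome genes, -0.164 for the unfolded protein response, -0.133 for extracellular matrix and -0.132 for NRF2 genes.

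Single arrays lay far from the other 3 of their group for 13 of 223 group values of named genes, where chance gives about 1 in 20, and for 0 of 24 array measures. The gap to the nearest array, as a share of the group's range, was 0.923 for MELTF, 0.926 for NHSL3, 0.901 for ADAMTS1, 0.843 for JUND and 0.901 for HMGCS1 in EC on flat titanium. In EC on NT30 it was 0.911 for PPP1R14A, 0.932 for TPM2, 0.889 for UQCRH, 0.871 for CFL1 and 0.972 for NEAT1, and in EC on NT100 it was 0.981 for SLC32A1, 0.833 for CCN3 and 0.841 for CCR3.

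Probes without a current gene name, which the comparisons of genes leave out, also passed. In EC on NT100 it was 1 of 7378 such probes, higher, when all 26931 probes were tested, and in VSMC on NT30 it was 198 of 7303, 67 higher and 131 lower, among 1351 of 30585 probes.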

How the results depend on the processing

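Alternatives added after seeing the data were the interaction without both arrays that stood apart, the fit of the diameters with replicate number as a block on 8 arrays, the overlap of both changes with replicate numbers split, and, for lists, the slide block, normexp and leaving out arrays; where a value below changed and no reason is given, the cause was not tested. Of the genes followed, 1672 of 1747 values for 70 genes in EC on NT30 under 25 alternatives kept both direction and side of the threshold, as did 1454 of 1672 in EC on NT100, 1221 of 1230 between the diameters, 765 of 994 in VSMC, 1288 of 1467 for the interaction and 97 of 99 between cell types. The authors' values were not run for VSMC and the interaction, because their VSMC columns do not match the arrays by probe name. In EC on NT30 the count of 0 genes became 9 with quantile scaling, 1 with median scaling, 3 with probes well above background on every array, 1 with every probe tested, 291 with array weights, 22 with all 19 arrays and 0 to 6 with an array left out. The 11 genes of EC on NT100 became 0 with normexp, 6 with quantile scaling (5 shared), 0 without the filter on dim probes, 4 with median scaling (3 shared), 1 with every probe tested, 5 with the mean over probes (5 shared), 100 with array weights (11 shared), 61 with all 19 arrays (10 shared), 0 with the slide block, 0 with the 2 groups alone, 0 with each gene's own variance alone and 0 to 4 with an array left out. A stricter adjusted p below 0.01 left 0 and a log2 change of at least 1 left 6. Between the diameters 0 genes passed under each alternative. In VSMC the 991 genes became 148 with normexp (148 shared), 579 with quantile scaling (500 shared), 379 with median scaling (345 shared), 2084 with trend and robust settings (957 shared), 487 with the slide block (474 shared), 234 with all 19 arrays (218 shared), 191 at an adjusted p below 0.01, 159 with a log2 change of at least 1, and 238 to 1077 with an array left out. With replicate number as a block no gene passed, in VSMC or for the interaction. The 173 genes of the interaction became 23 with normexp, 27 with median scaling (26 shared), 275 with probes well above background on every array (166 shared), 267 with trend and robust settings (169 shared), 719 with array weights (173 shared), 83 with all 19 arrays (81 shared), 34 at an adjusted p below 0.01, 88 with a log2 change of at least 1, and 83 to 290 with an array left out; it was 143 without both arrays that stood apart. The 10423 genes between cell types became 4691 with normexp and 9698 to 11140 with an array left out.

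Lists depended on the correlation assumed within a list. With an estimated correlation 1, 1, 0, 0 and 0 lists passed for EC on NT30, EC on NT100, the diameters, VSMC and the interaction, and with fry 1, 2, 0, 0 and 0, against 16, 15, 9, 5 and 9. Between the diameters 4 passed with quantile scaling and 5 with the slide block, and 16 passed for the interaction with normexp. With an array left out the ranges were 9 to 15, 10 to 15, 2 to 12, 5 to 9 and 6 to 12. The correlation of the NT30 and NT100 changes fell from 0.845 to 0.328 and their covariance from 0.0621 to 0.033 when the flat arrays were split, which removes the shared controls, and to 0.232 and 0.0281 when replicate numbers were split as well.

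NT30 and NT100 arrays of EC with the same number deviated together, as seen from the values (r above 0.1 in 4 of 4 pairs). Yet NT30 replicate 2 lay closer to NT100 replicate 3 (r = 0.311 against 0.145), and NT30 replicate 3 to NT100 replicate 4 (0.388 against 0.286). Both of these closer pairs shared a slide, so pairing by number is not settled. Replicate numbers did not pair flat titanium with NT30 (1 of 4 pairs, -0.0695 to 0.283) or NT100 (3 of 4, -0.269 to 0.446) in EC, or the VSMC groups (2 of 3, -0.0535 to 0.393), and 5 of 12 EC and 2 of 7 VSMC arrays were closest to their own number. With number as a block in a fit to the 8 nanotube arrays, 0 genes and 7 lists differed between the diameters: hypoxia and lysosome genes lost their calls (adjusted p = 0.0562 and 0.0568) and the block changed no other call there. With replicate number as a block on all arrays of each fit the counts were 9 genes in EC on NT30, 34 in EC on NT100 (10 shared), 0 in VSMC and 0 for the interaction.

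Over all genes followed, whether or not the text names them, the sign changed in 19 values of 15 genes in EC on NT30, 12 of 8 in EC on NT100, 9 of 5 between the diameters, 1 in VSMC and 3 of 3 for the interaction. Values below are those of genes that the text names, none of which passed with the changed sign, and of lists. In EC on NT30 normexp gave SLC32A1 -0.0619, CCN3 -0.00752, OASL -0.146 and GAPDH 0.19, and adjusted p = 0.991 for the fibroblast list and 0.0152 for oxidative phosphorylation, both in the opposite direction. ACTB was -0.0036 with quantile scaling, -0.0455 with the authors' values, -0.18 with the mean over probes and -0.00238 without EC on flat titanium replicate 3 (up to 0.248 with other arrays left out), and GAPDH 0.0229 without replicate 1 (down to -0.126). In EC on NT100 normexp gave SLC32A1 -0.038, EDNRB -0.0309 and adjusted p = 0.0442 for oxidative phosphorylation. ACTB was -0.013 with quantile scaling, -0.11 with the authors' values and -0.13 with the mean over probes, and GAPDH -0.0208 with the authors' values, -0.0185 with array weights and -0.06003 without EC on flat titanium replicate 3 (up to 0.0885). Between the diameters ACTB was -0.0094 with quantile scaling, -0.067 with the authors' values and -0.0561 without NT100 replicate 1 (up to 0.223), and leaving out NT30 replicate 1 turned the lists G1/S (adjusted p = 0.113, from 1.77e-10 to 0.516 over arrays left out), G2/M (0.0658, from 3.26e-13 to 0.107) and lysosome (0.99, from 0.011). SPMAP2 in VSMC was -0.15 with normexp, and in the interaction ACTB was 0.0042 with the mean over probes and GAPDH 0.045 without both arrays. Signal over background limits the dim genes: median raw signal was 1.78 to 2.79 times that of negative controls on EC arrays and 7.3 to 11.89 times on VSMC arrays.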

Other observations

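Between the cell types on flat titanium, beyond the single markers, all 14 measured genes of the fibroblast and mesenchymal list were higher in VSMC (camera adjusted p = 1.22e-08; adjusted p = 0.133 with an estimated correlation). Extracellular matrix genes were higher in 32 and lower in 9 of 44 (adjusted p = 1.19e-07; adjusted p = 0.0966 with an estimated correlation), hypoxia and glycolysis genes higher in 25 of 31 (median log2 0.975, adjusted p = 8.77e-08; adjusted p = 0.193 with an estimated correlation) and replication-dependent histones in 11 of 12 (adjusted p = 7.23e-06; adjusted p = 0.193 with an estimated correlation). Lower in VSMC were 20 of 25 endothelial identity genes (median -6.22, adjusted p = 3.21e-08), 20 of 25 junction genes (-2.45, 1.24e-05) and 19 of 28 genes of angiogenesis and Notch signalling (adjusted p = 0.0029), each with adjusted p = 0.133 with an estimated correlation. Array design and scan coincide with cell type in all of these.

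The mean of each list over its members was also compared between groups by exact permutation of the arrays, a test chosen after the data were seen, over 70 splits for EC and 35 for VSMC, where the smallest possible p is 0.0286. On NT30 in EC it was reached by contractile genes (-0.394), actin cytoskeleton genes (-0.228), immediate early genes (0.46) and the unfolded protein response (0.179), with 0.243 after adjustment over the lists. On NT100 it was reached by contractile genes (-0.366), immediate early genes (0.538), matrix proteases (0.206), vasoactive genes (0.174), actin cytoskeleton genes (-0.172) and coagulation genes (0.151), with 0.162 after adjustment. Contractile and actin cytoskeleton lists share members, so they are not separate results. In VSMC it was reached by G2/M genes (0.665), metallothioneins (0.263), hypoxia and glycolysis genes (-0.151) and integrins and focal adhesion genes (-0.107), with 0.243 after adjustment. No list passed in these 3 comparisons by this test alone, which its smallest possible p makes nearly out of reach over 34 lists, while 23 passed between the cell types on flat titanium (adjusted p = 0.0423).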
